A study of Mus musculus with 30 samples.

How the data were processed

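RNA from mouse neurospheres of 3 culture conditions (6 samples with EGF, 6 with PDGF-AA and 3 with PDGF-AA and NT-3) was measured on a pair of Affymetrix arrays, MOE430A and MOE430B, giving 30 arrays for 15 RNA samples. Per the labels' protocols, cells were grown for 7 days in DMEM:F12 with N2 and B27, RNA was prepared with RNeasy without amplification, and biotinylated cRNA was made by the manufacturer's protocol. The labels give PDGF-AA at 100 ng/ml for the PDGF samples and both factors at 100 ng/ul for the PDGF and NT-3 samples, a unit that could not be checked. The growth protocol of the EGF samples also names PDGF-AA, and their grouping follows their titles, descriptions and purification protocol. RNA concentrations per the labels were 100 ng/ul for the EGF and PDGF samples and 192, 287 and 171 ng/ul for the samples with NT-3. Whether replicates were separate cultures, the number of embryos and their sex are not given in the sources used here.

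The deposited values are probe set signals on a linear intensity scale, made with MAS5 per the submitters' processing notes, whose version is not given in the sources used here. The values show that each array was scaled to a common level: the mean of every array, with 2% trimmed at each end, lay between 1500.2 and 1500.77. Detection calls and raw images are not used here. Scanner and fluidics settings of each array were read only to find arrays processed together. No pair of arrays held identical values (0 pairs).

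The chips hold 22690 and 22575 probe sets. Gene symbols came from the platform tables, in which 35041 probe sets have 1 symbol, and 34837 of these matched the RefSeq genes of assembly GRCm38.p6, used for names only. Probe sets with several symbols (691 and 245), with none (1555 and 7605) and control probe sets (64 on each chip) stayed out of the gene tests. A probe set was kept when its signal was at or above the array's median in at least 3 of the 15 arrays of its chip (29796 probe sets, 23595 with 1 symbol). Each gene was represented by 1 probe set, taken from MOE430A where it had one and otherwise from MOE430B, and among several by the highest mean log2 signal. This left 13882 genes (8534 and 5348 per chip), 4446 of which had several probe sets.

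Signals were transformed as log2 of signal plus a pseudocount, the 10th percentile of the chip's values (52.0 and 115). The authors' scaling was kept. Both chips were stacked under the same 15 samples and fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts and eBayes with trend, 12 residual degrees of freedom; data.table, version 1.17.8, for reading files). The 3 pairs of conditions were compared, and p-values, all two-sided, were adjusted by Benjamini and Hochberg over all genes of a comparison, with a threshold of 0.05. Differences are coded EGF minus PDGF, PDGF with NT-3 minus PDGF, and EGF minus PDGF with NT-3. Samples were not treated as paired. Fold changes are 2 to the power of the log2 difference and so include the pseudocount. Median signals of the chips were 555 and 866.

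Before the data were examined, the comparisons, the rule for named genes, most alternatives and 30 gene lists were fixed. The lists were written from general knowledge: cell types and stages of the neural lineage, forebrain regions, signalling pathways, cell cycle, metabolism and stress, extracellular matrix, glutamate receptors, imprinted genes, other cell types, and sex-linked genes. The sex list served only to check samples and the list of red blood cell genes was too short for the camera test below, which left 28 lists. Shifts were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists and comparisons together. Beside it stand camera with an estimated correlation, limma's fry, and the place of a list's median among 10000 random lists of matched mean signal. The random lists were added after the data were seen. Fry was adjusted within each comparison alone, over its lists together with that of red blood cells. Counts adjusted over the list alone use the list's own p-values.

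Genes named in the text follow the fixed rule. These are the 12 genes with the largest increase and the 12 with the largest decrease (6 each for EGF against PDGF with NT-3), among genes past the threshold whose samples do not overlap between conditions and whose mean signal in the higher condition reaches the chip's median. Added to them are the receptors Egfr, Pdgfra, Ntrk3, Ntrk2 and Ngfr and up to 4 members per described list, those with the smallest adjusted p, with both directions represented. Describing members only for lists that passed camera was settled after the results were seen. Genes plotted were picked from the named ones after the results were seen.

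RNA quality was compared by the log2 ratio of the 3' to the 5' control probe sets of Actb and Gapdh on each chip, by exact permutation of the samples (12 tests). EGF and PDGF arrays fell into 3 fluidics runs with 2 samples of each condition each, so this comparison was repeated with the run as a block and within each run. The arrays with NT-3 shared no run with the others (0 arrays). On the first chip NT-3 replicate 3 was in another run than replicates 1 and 2, and on the second chip all replicates with NT-3 shared a run.

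The procedure was tested on simulated data with 200 of the 13882 genes changed. At a log2 change of 2, 86.5% were recovered for EGF against PDGF, 80% for PDGF with NT-3 against PDGF and 74% for EGF against PDGF with NT-3, with 6.99%, 5.88% and 4.52% false calls. At a log2 change of 1 the shares were 48.5%, 33.5% and 33%, with 4.9%, 2.9% and 1.49% false calls, so many changes of that size are missed here. A simulated list of 18 genes shifted by 0.7 for EGF against PDGF was called in 20 of 20 simulations, and other lists in 0 of 540. The simulated genes were independent of each other, so these counts do not measure false list calls among correlated genes. All simulated samples of a gene had the same spread, whereas the real samples with NT-3 differed more from each other than other replicates did. The shares recovered and false calls given for the comparisons with NT-3 may therefore not hold for the real data.

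Alternatives tried were other pseudocounts, other filters, quantile scaling and median centring, the replicate number as a block, only the conditions compared, each chip alone, the mean of a gene's probe sets, all probe sets, eBayes without trend or robust, array weights, the fluidics run as a block, a 2-fold minimum, other probe sets of each named gene, and leaving out each sample. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.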

Results

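Gene expression was measured in mouse neurospheres, which are floating clusters of dividing neural precursors, started from the ventral forebrain at embryonic day 14 and grown for 7 days. Neurospheres grown with PDGF-AA, the ligand of Pdgfra, came from the anterior entopeduncular area (6 RNA samples), and so did those grown with PDGF-AA and neurotrophin-3 (NT-3, the ligand of Ntrk3; 3 samples). Neurospheres grown with EGF, the ligand of Egfr, came from the medial and lateral ganglionic eminences (6 samples). The growth protocol in the labels of the EGF samples names PDGF-AA, while their titles, descriptions and purification protocol name EGF. They are treated here as EGF samples. Each RNA sample was hybridised to a pair of arrays that carry different genes, and 13882 genes were tested. Values below are log2 fold changes ± SE, means are array signals ± SD, and the tests are two-sided.

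On the first 2 principal components the 15 samples grouped by condition, but the 3 samples with NT-3 differed more from each other than other replicates did. Their pairs correlated at 0.825 to 0.852, below the highest EGF with PDGF pair (0.871), and on PC3 (8.86% of the variance) replicates 2 and 3 lay at −56.9 and 58.3. Replicates 1 and 2 shared their fluidics runs on both chips, though replicate 1 lay at −3.42 on PC3. Replicate 3 was in another run on the first chip. Across genes, which are not independent replicates, the median correlation between samples was 0.892 within PDGF, 0.890 within EGF and 0.850 within PDGF with NT-3, against 0.844 between EGF and PDGF, 0.808 between PDGF with NT-3 and PDGF, and 0.799 between EGF and PDGF with NT-3. The labels do not say whether the replicates of a condition came from separate cultures, so the p-values measure the spread between these samples. That spread was estimated for each gene from all 15 samples together, of which 3 were with NT-3. With only the 2 conditions compared, 2266 genes passed for PDGF with NT-3 against PDGF, against 2943 with all samples. For EGF against PDGF with NT-3 these counts were 2564 and 3119, and for EGF against PDGF 2028 and 1807.

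**Figure D1:**
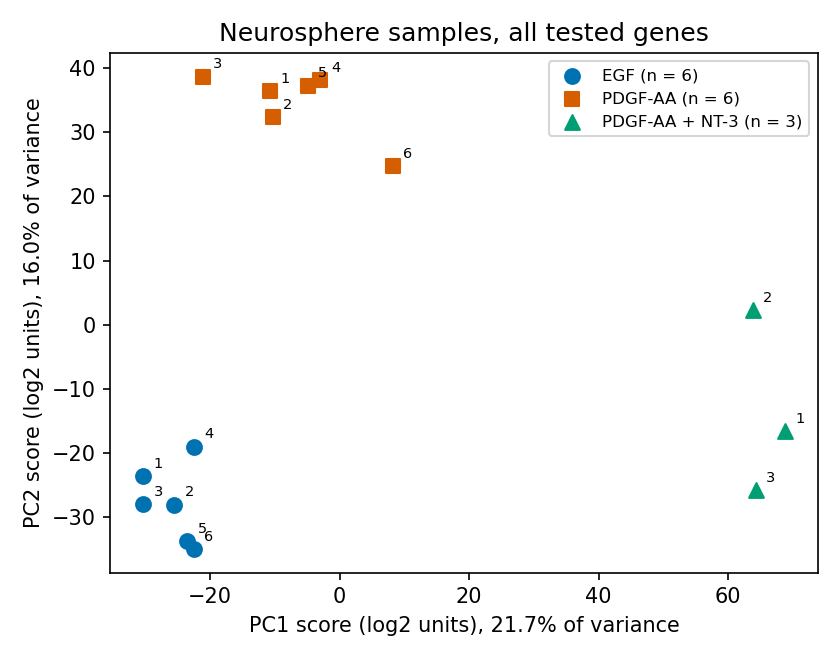
Principal component scores (log2 units) of the 15 samples over the 13882 tested genes, 1 point per sample with its replicate number, PC1 on the horizontal and PC2 on the vertical axis. PC1 (21.7% of the variance) sets the 3 samples with NT-3, at 63.8 to 68.9, apart from all others, at 8.23 or lower, and PC2 (16%) separates EGF from PDGF.

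EGF neurospheres carried more RNA of astrocyte and radial glia genes than PDGF neurospheres, and less of oligodendrocyte progenitor genes. Pan-neuronal and glutamate receptor genes were lower too, lists that did not pass when the correlation between genes was estimated (adjusted p = 0.134 and 0.0687 with an estimated correlation). Pdgfra, the receptor for the factor that the PDGF cultures received, was among the most strongly lower genes with EGF. Egfr gave no single answer, because its probe sets differed. With EGF relative to PDGF, 902 genes were higher and 905 lower (1807 of 13882, 13.0%), of which 694 differed at least 2-fold. The factor and the brain region of origin differ together in this comparison, so the values belong to the pair.

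Among the largest increases with EGF, Mlc1, a membrane protein of astrocytes, rose (5.79 ± 0.27, adjusted p = 2.72e-10), from 41.3 ± 15, under the pseudocount of 52.0 that was added before the logarithm, to 5117 ± 857 in signal. Gja1, the astrocyte gap junction protein connexin 43, rose 19.4-fold (4.28 ± 0.28, adjusted p = 2.4e-08; 465 ± 285 to 9171 ± 2403). Igfbp2, a secreted binding protein of insulin-like growth factors, rose 17.7-fold (4.14 ± 0.16, adjusted p = 3.44e-11; 1299 ± 279 to 23778 ± 5012). The carbonic anhydrase Car3 (5.14 ± 0.28), the lysosomal protease Ctsc (4.67 ± 0.23), the phospholipase Pla2g7 (4.55 ± 0.30; 27.9 ± 14.5 in PDGF, also under the pseudocount), the troponin Tnnt1 (4.46 ± 0.40) and the galectin Lgals1 (4.16 ± 0.21) followed. The secreted protease Htra1 (4.01 ± 0.35), the laminin receptor subunit Itga6 (4.0 ± 0.39), the annexin Anxa5 (3.94 ± 0.33) and Lrig1, a membrane inhibitor of Egfr signalling (3.90 ± 0.32), completed the 12 largest. For Mlc1 and Pla2g7 the size of the change, though not its direction, therefore rests on the pseudocount (4.66 to 6.97 and 3.34 to 6.07 with other pseudocounts). Tnnt1 and Htra1 also lay under the 25th percentile of the arrays with PDGF. Other probe sets of Car3 and Lrig1 gave −0.0078 and −0.023 and did not pass.

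Among the largest decreases with EGF, Pdgfra fell 10.9-fold (−3.44 ± 0.14, adjusted p = 6.3e-11), from 10992 ± 1005 to 979 ± 217, and Sox10, a transcription factor of the oligodendrocyte lineage, fell 7.79-fold (−2.96 ± 0.22, adjusted p = 7.38e-08; 8312 ± 1394 to 1081 ± 437). Zic1, a transcription factor of the septum and ventral midline, fell 9.32-fold (−3.22 ± 0.35, adjusted p = 5.6e-06), and Hapln1, which links hyaluronan to proteoglycans, 9.86-fold (−3.30 ± 0.46, adjusted p = 8e-05). The transcript AW551984 (−3.43 ± 0.39), the secreted neuropeptide precursor Vgf (−2.86 ± 0.38), the myelin glycoprotein Omg (−2.78 ± 0.38) and the bicarbonate transporter Slc4a10 (−2.65 ± 0.46) were next. Brinp3 (−2.55 ± 0.29), Tmem130 (−2.52 ± 0.31), Capn6 (−2.45 ± 0.39) and Jakmip1 (−2.41 ± 0.50) closed the 12 largest. The naming rule required these 24 genes to have EGF and PDGF samples that do not overlap. Of all 1807 genes called, 1088 had such samples. Slc4a10 and Brinp3 lay under the 25th percentile of the arrays with EGF, so the pseudocount sets part of their size. Without the filter on signal another probe set stands for Hapln1, and that probe set did not pass (−0.17, adjusted p = 0.839).

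Among 28 gene lists, 14 shifted against the other genes by limma's camera test with its preset correlation, and 3 of these held with an estimated correlation: oligodendrocyte progenitors, radial glia and astrocytes. Of the 23 oligodendrocyte progenitor genes, 15 were lower with EGF and 0 higher (15 and 0 adjusted over the list alone; median −0.86, adjusted p = 5.11e-11, and 0.0267 with an estimated correlation). They include Gpr17 (−1.77 ± 0.16) and the matrix protein Matn4 (−2.14 ± 0.23) beside Pdgfra and Sox10. Of the 18 astrocyte genes, 12 were higher and 1 lower (14 and 1 adjusted over the list alone; median 1.14, adjusted p = 2.2e-11, and 0.0186 with an estimated correlation). Gja1, the bicarbonate cotransporter Slc4a4 (3.13 ± 0.22) and Id3 (1.92 ± 0.16) rose, and the calcium-binding protein S100b fell (−1.31 ± 0.25). Of the 21 genes of radial glia and neural stem cells, 8 were higher and 0 lower (9 and 1 adjusted over the list alone; median 0.38, adjusted p = 3.41e-05, and 0.0448 with an estimated correlation). The glutamate transporter Slc1a3 (2.42 ± 0.16), the metallothionein Mt3 (3.45 ± 0.25), the stem cell surface protein Prom1 (2.11 ± 0.20) and the growth factor Ptn (0.83 ± 0.13) rose.

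Neuronal genes were lower with EGF. Of 19 pan-neuronal genes, 13 were lower and 0 higher (14 and 0 adjusted over the list alone; median −0.89, adjusted p = 8.56e-09, and adjusted p = 0.134 with an estimated correlation). The lower genes were led by the RNA-binding protein Elavl4 (−1.55 ± 0.19), Stmn3 (−1.38 ± 0.17), the growth cone protein Gap43 (−1.27 ± 0.17) and the microtubule protein Mapt (−1.46 ± 0.22). Of 17 genes of GABAergic and ventral telencephalic neurogenesis, 5 were lower (7 adjusted over the list alone; median −0.50, adjusted p = 0.00401, and adjusted p = 0.239 with an estimated correlation). The progenitor factor Gsx1 (−2.20 ± 0.38), the interneuron factor Lhx6 (−1.42 ± 0.32), the enzyme Gad1 (−1.50 ± 0.36) and the transporter Slc32a1 (−0.94 ± 0.27) fell, all 4 with samples that overlapped. Slc32a1 did not pass without PDGF replicate 4, 5 or 6 or EGF replicate 2, 3 or 5 (adjusted p from 0.0518 to 0.0699). Ionotropic glutamate receptors fell in 3 of 13 genes (3 adjusted over the list alone; median −0.57, adjusted p = 0.00573, and adjusted p = 0.0687 with an estimated correlation). Without EGF replicate 2 the median was −0.34, and without the filter on signal −0.32. The 3 genes were Gria2 (−1.05 ± 0.16), Grik1 (−1.70 ± 0.28) and Gria3 (−1.40 ± 0.31).

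Of 12 lateral ganglionic eminence genes, 5 were higher with EGF (5 higher and 1 lower adjusted over the list alone; median 0.68, adjusted p = 0.00645, and adjusted p = 0.0685 with an estimated correlation). The homeobox genes Meis2 (1.60 ± 0.19), Meis1 (2.52 ± 0.31) and Six3 (0.81 ± 0.19) and the forkhead gene Foxp1 (1.08 ± 0.22) were among them. Notch pathway genes were higher in 6 and lower in 1 of 18 (7 and 2 adjusted over the list alone; median 0.35, adjusted p = 0.00626, and adjusted p = 0.134 with an estimated correlation). Notch2 (2.21 ± 0.23), Lfng (1.14 ± 0.25) and Hes6 (0.99 ± 0.19) rose and the ligand Dll3 fell (−0.58 ± 0.17). Hedgehog pathway genes were higher in 4 of 9 (6 adjusted over the list alone; median 0.60, adjusted p = 0.000216, and adjusted p = 0.0601 with an estimated correlation). They were the co-receptors Gas1 (1.48 ± 0.23) and Cdon (1.28 ± 0.17), Gli3 (0.99 ± 0.17) and Smo (0.78 ± 0.16). Wnt pathway genes were higher in 4 of 20 (4 adjusted over the list alone; median 0.22, adjusted p = 0.0309, and adjusted p = 0.0917 with an estimated correlation). They were Wnt5a (1.79 ± 0.39), Wnt7a (1.10 ± 0.22), Nkd1 (0.69 ± 0.19) and Fzd1 (0.61 ± 0.13). Without the filter on signal the Hedgehog and Wnt lists did not pass (medians 0.19 and 0.19, adjusted p = 0.142 and 0.219) and Cdon (−0.27) and Gli3 (−0.26), then read from another probe set, had the opposite sign, while Fzd1 (0.52, adjusted p = 0.666) and Nkd1 (0.30, adjusted p = 0.822) did not pass. Other probe sets of Notch2 (−0.10), Foxp1 (−0.45), Smo (−1.30) and Wnt7a (−0.26) also had the opposite sign. With a stricter filter, at the 75th percentile, another probe set stands for Meis1 and did not pass (0.12, adjusted p = 0.677); the chosen one lay under the 25th percentile of the arrays with PDGF. Dll3 did not pass without PDGF replicate 3 or 5 or EGF replicate 6 (adjusted p = 0.0534, 0.0582 and 0.0563), nor Nkd1 without PDGF replicate 4 or 5 or EGF replicate 6 (adjusted p = 0.0509, 0.0519 and 0.0545) or with each chip alone (0.0657). As the mean of their probe sets Hes6 (adjusted p = 0.0626) and Smo (0.274) did not pass.

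Cell cycle genes of S and G2/M phase were higher with EGF in 9 of 31 (13 adjusted over the list alone; median 0.39, adjusted p = 1.24e-06, and adjusted p = 0.134 with an estimated correlation). Named by the rule were the ribonucleotide reductase subunits Rrm2 (0.77 ± 0.13) and Rrm1 (0.59 ± 0.13; 0.39, adjusted p = 0.0657, as the mean of its probe sets) and the mitotic genes Bub1b (0.84 ± 0.16) and Cdca8 (0.81 ± 0.15). Genes that respond to the ERK pathway were higher in 7 and lower in 2 of 16 (7 and 3 adjusted over the list alone; median 0.27, adjusted p = 0.0466, and adjusted p = 0.154 with an estimated correlation). Ier3 (1.65 ± 0.22), the phosphatase Dusp6 (1.56 ± 0.18) and the ligand Hbegf (1.41 ± 0.15) rose and Phlda1 fell (−1.35 ± 0.14). The list did not pass without PDGF replicate 1, 4 or 5 or EGF replicate 6 (adjusted p = 0.0579, 0.0631, 0.0502 and 0.0692), and without the filter on signal its median was 0.12. Cholesterol synthesis genes were lower in 4 of 18 (7 adjusted over the list alone; median −0.25, adjusted p = 0.0117, and adjusted p = 0.342 with an estimated correlation). They were Msmo1 (−0.65 ± 0.15), Idi1 (−0.47 ± 0.10), Srebf2 (−0.46 ± 0.12; 0.089 on another probe set) and Cyp51 (−0.44 ± 0.12). Srebf2 and Cyp51 did not pass with median centring (adjusted p = 0.0950 and 0.0610) or as the mean of their probe sets (0.568 and 0.404). Imprinted genes were higher in 1 and lower in 6 of 12 (1 and 7 adjusted over the list alone; median −0.61, adjusted p = 0.00145, and adjusted p = 0.213 with an estimated correlation). Mest rose (1.89 ± 0.17), and Ndn (−1.45 ± 0.15), Nnat (−1.33 ± 0.24) and Peg3 (−0.65 ± 0.13) fell.

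Of the receptors, Ntrk2 was higher with EGF (1.13 ± 0.09, adjusted p = 2.46e-07), and 4 of its other probe sets had the opposite sign (−0.84 to −0.20). Egfr did not pass on the probe set chosen by the rule (−0.32 ± 0.20, adjusted p = 0.363), while 2 of its other probe sets were higher (3.25, adjusted p = 0.000179, and 3.18, adjusted p = 8.73e-10). Ngfr did not differ detectably (−0.06 ± 0.55, adjusted p = 0.972). Ntrk3 did not pass on the chosen probe set (−0.39 ± 0.37, adjusted p = 0.598), but was lower with EGF on the brighter probe set that a 75th percentile filter picks (−0.62, adjusted p = 0.00555).

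EGF and PDGF samples were processed together in 3 fluidics runs, each with 2 samples of each condition, so the comparison can be made within runs. With the run as a block, in a fit of the EGF and PDGF samples alone, 2056 genes passed (1012 higher, 1044 lower). The same samples without the block gave 2028. Within single runs 220, 291 and 270 genes were higher and 134, 164 and 225 lower. Within runs, Mlc1 ranged from 5.59 to 6.09 and Pdgfra from −3.83 to −3.19. The run medians ranged from −1.04 to −0.85 for oligodendrocyte progenitors, 1.06 to 1.33 for astrocytes, 0.35 to 0.49 for radial glia, −1.13 to −0.70 for pan-neuronal genes and −0.90 to −0.43 for GABAergic genes. They ranged from 0.41 to 0.71 for the lateral ganglionic eminence, 0.24 to 0.54 for the cell cycle, 0.09 to 0.46 for Notch, 0.52 to 0.63 for Hedgehog and 0.19 to 0.43 for Wnt genes. The ranges were −0.27 to −0.26 for cholesterol synthesis, −0.66 to −0.29 for glutamate receptors, −0.78 to −0.46 for imprinted genes and 0.24 to 0.36 for ERK genes. With the run as a block, and adjusted over the 28 lists of this comparison alone, 13 of the 14 lists passed. The ERK list did not (adjusted p = 0.0548).

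**Figure D2:**
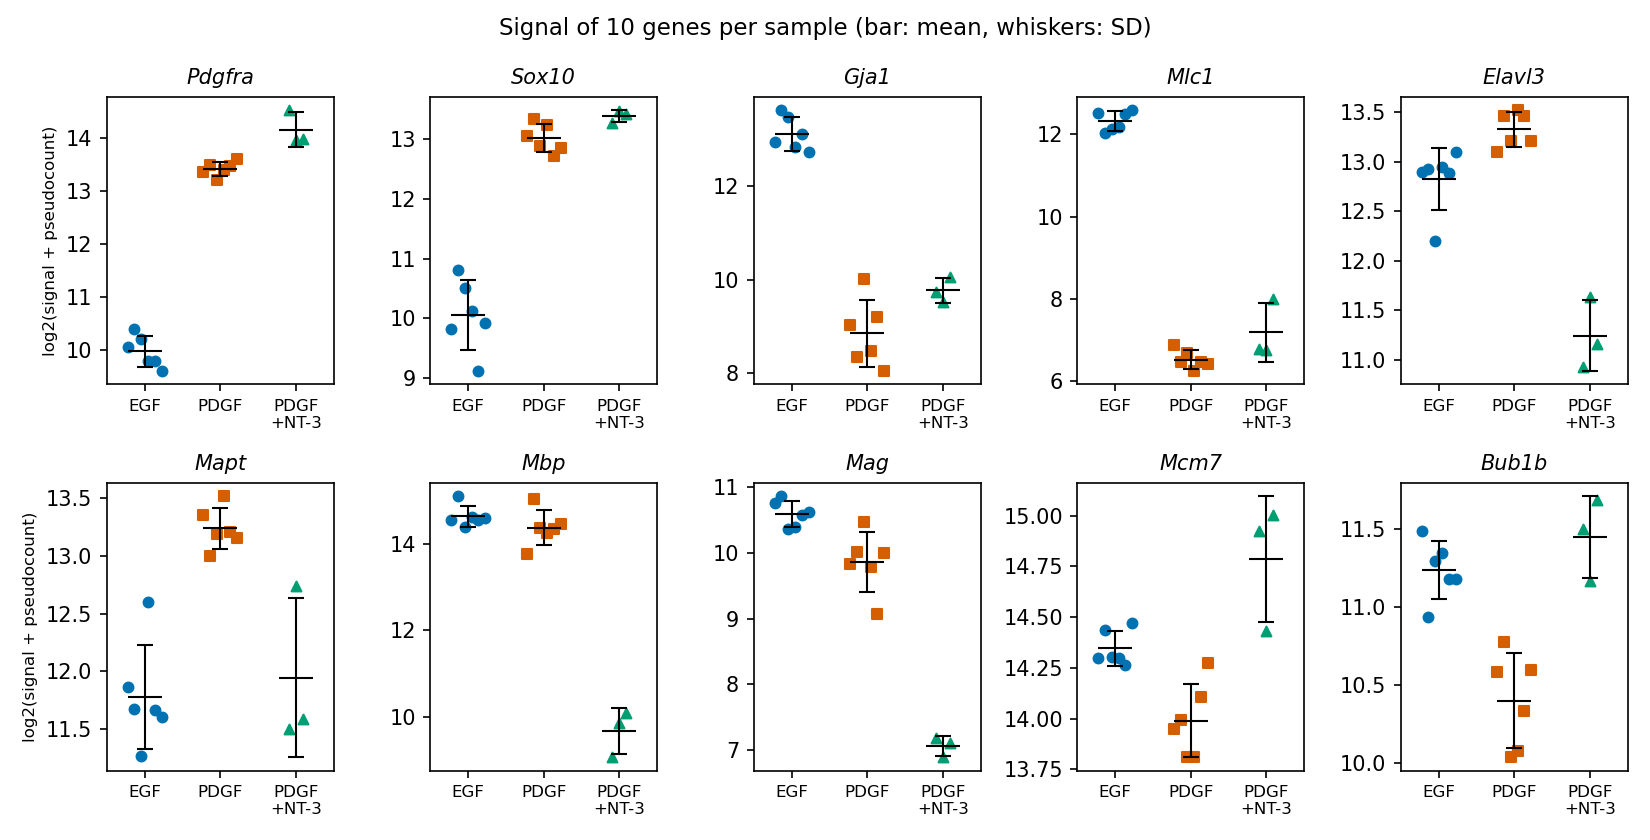
Log2 signal (with the chip's pseudocount added) of 10 genes in each sample, by condition on the horizontal axis; points are samples, bars are means and whiskers SD. Mean log2 signal of Mbp is 14.63 with EGF, 14.36 with PDGF and 9.68 with PDGF and NT-3, and that of Pdgfra is 9.98, 13.43 and 14.16.

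Mbp, which encodes a main structural protein of myelin, and the myelin genes Mag and Mal were among the most strongly lower genes when NT-3 was added to PDGF. As lists, myelin and pan-neuronal genes were lower and cell cycle genes higher. None of these lists passed when the correlation between genes was estimated (adjusted p = 0.0917, 0.275 and 0.0687 with an estimated correlation). With PDGF and NT-3 relative to PDGF alone, 1031 genes were higher and 1912 lower (2943 of 13882, 21.2%), of which 1454 differed at least 2-fold. Without NT-3 replicate 1 the higher genes numbered 662, and with array weights 616 were higher and 1897 passed in total. The samples with NT-3 were hybridised apart from the others, sharing 0 fluidics runs with them, so the hybridisation batch and the condition cannot be told apart.

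Mbp fell 25.7-fold (−4.68 ± 0.24, adjusted p = 4.11e-09), from 21697 ± 6370 to 803 ± 284. Its 5 bright probe sets ranged from −4.75 to −3.29, and its 3 dim ones (−1.27, −0.93 and 0.62) did not pass. Mal, a myelin membrane protein, fell too (−3.10 ± 0.33, adjusted p = 1.94e-05; 1194 ± 375 to 93.5 ± 52.7), and Mag, an adhesion molecule of the inner myelin membrane (−2.80 ± 0.29, adjusted p = 1.49e-05; 914 ± 282 to 82.1 ± 14.1). Hr, a corepressor of nuclear receptors, fell (−3.50 ± 0.35, adjusted p = 1.46e-05; −4.11 to −2.98 leaving out single samples). The transporter Slc45a2 (−3.28 ± 0.43), the coactivator Ncoa3 (−3.22 ± 0.33; −0.24, adjusted p = 0.392, on the probe set that a 75th percentile filter picks), the actin nucleator Spire2 (−3.05 ± 0.45), the helicase Rtel1 (−3.04 ± 0.31) and the focal adhesion protein Parvb (−2.99 ± 0.25) followed. The synaptic protein Clstn3 (−2.96 ± 0.61), the neuropeptide Cort (−2.86 ± 0.52) and the noncoding RNA Cerox1 (−2.85 ± 0.39) completed the 12 largest decreases. Leaving out single samples moved Slc45a2 to as low as −4.11, Clstn3 between −4.10 and −2.29 and Cerox1 between −3.47 and −2.07. With NT-3 the signals of Mal, Mag, Ncoa3, Spire2 and Cort lay under the 25th percentile of the arrays (143), so the pseudocount sets part of the size: with other pseudocounts Mal ranged from −3.74 to −2.36 and Mag from −3.41 to −2.08.

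Among the 12 largest increases, Pik3cd, a catalytic subunit of PI3-kinase, rose 7.14-fold (2.84 ± 0.17, adjusted p = 2.46e-08; 28632 ± 3599 to 210248 ± 65216), Eepd1 (2.88 ± 0.49, adjusted p = 0.000825; 251 ± 54.1 to 2556 ± 170) rose as well, and the matrix protein Sparc rose 5.16-fold (2.37 ± 0.38, adjusted p = 0.000529). The others were 1700003E16Rik (3.09 ± 0.52), the lipid flippase Atp10b (2.90 ± 0.41), the innate immune adaptor Sting1 (2.79 ± 0.62), the transcription factors Sall3 (2.69 ± 0.45) and Pknox1 (2.40 ± 0.41), Depp1 (2.63 ± 0.45), 4930503L19Rik (2.56 ± 0.44), the signalling regulator Ski (2.47 ± 0.62) and the mitochondrial carrier Slc25a32 (2.40 ± 0.50). The naming rule required these 24 genes to have samples that do not overlap between the conditions. Of all 2943 genes called, 2159 had such samples. Other probe sets had the opposite sign for Pik3cd (−0.16), Depp1 (−0.32), Sparc (−0.17), Mal (0.34) and Rtel1 (0.24). Without the filter on signal another probe set stands for some of these genes, giving −0.50 for Eepd1, −0.76 for Pik3cd and 0.034 for Parvb, and Sting1, 4930503L19Rik, Pknox1 and Slc25a32 did not pass (adjusted p from 0.0985 to 0.444). With PDGF the signals of Eepd1, Sting1, 4930503L19Rik and Slc25a32 lay under the 25th percentile of the arrays.

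By camera 6 of 28 lists shifted. With an estimated correlation 0 did after adjustment, and 5 lists had an unadjusted p under 0.05. Among these 5 were the dorsal telencephalon (0.0440) and ERK lists (0.0471), which the preset correlation did not call. The pan-neuronal (0.102), GABAergic (0.0840) and cholesterol synthesis lists (0.149), called with the preset correlation, were not among them. Of 17 genes of maturing oligodendrocytes and myelin, 9 were lower and 0 higher (9 and 0 adjusted over the list alone; median −0.97, adjusted p = 7.07e-06, and adjusted p = 0.0917 with an estimated correlation). Enpp6, a marker of newly formed oligodendrocytes, fell (−1.84 ± 0.28) beside Mbp, Mag and Mal. The oligodendrocyte progenitor list did not move as a group: 4 of its 23 genes were higher and 6 lower (5 and 6 adjusted over the list alone; median 0.03, mean −0.15, adjusted p = 0.491). Of 19 pan-neuronal genes, 10 were lower and 0 higher (10 and 0 adjusted over the list alone; median −1.03, adjusted p = 0.000104, and adjusted p = 0.275 with an estimated correlation). Elavl3, an RNA-binding protein of neurons, fell 4.24-fold (−2.08 ± 0.19, adjusted p = 5.84e-06; 10302 ± 1249 to 2426 ± 634), beside Syn1 (−2.43 ± 0.49; −1.39 without NT-3 replicate 3 and −3.13 without replicate 2), Rbfox3 (−1.81 ± 0.38; −1.39, adjusted p = 0.0907, without the filter on signal) and Mapt (−1.29 ± 0.26). Of 17 genes of GABAergic and ventral telencephalic neurogenesis, 7 were lower (7 adjusted over the list alone; median −0.68, adjusted p = 0.00645, and adjusted p = 0.261 with an estimated correlation). Without NT-3 replicate 2 the median was −1.24. The lower genes include Maf (−2.04 ± 0.36), Lhx6 (−1.88 ± 0.39), the neuropeptide Npy (−1.72 ± 0.32) and Slc32a1 (−1.39 ± 0.33; adjusted p = 0.0572 without NT-3 replicate 1). Maf, read from another probe set without the filter on signal, gave 0.92.

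Cell cycle genes moved the other way. Of 31 genes, 17 were higher with NT-3 and 0 lower (21 and 0 adjusted over the list alone; median 0.60, adjusted p = 1.49e-10, and adjusted p = 0.0687 with an estimated correlation). Among them were the replication licensing genes Mcm7 (0.80 ± 0.13; 16320 ± 2079 to 28648 ± 5791) and Cdc6 (1.36 ± 0.29) and the mitotic genes Bub1b (1.05 ± 0.20) and Ube2c (1.02 ± 0.20). Cholesterol synthesis genes were higher in 6 and lower in 1 of 18 (6 and 1 adjusted over the list alone; median 0.21, adjusted p = 0.0126, and adjusted p = 0.347 with an estimated correlation). Dhcr7 (1.21 ± 0.29), Fdft1 (0.95 ± 0.15) and Lss (0.88 ± 0.16) rose and Fdps fell (−0.83 ± 0.19; −0.54 without NT-3 replicate 1). Genes of endoplasmic reticulum and amino acid stress were higher in 4 and lower in 2 of 19 (4 and 2 adjusted over the list alone; median 0.23, adjusted p = 0.0380, and adjusted p = 0.134 with an estimated correlation). Sesn2 (1.27 ± 0.30), the amino acid transporter Slc7a5 (0.79 ± 0.23; 0.44, adjusted p = 0.173 without NT-3 replicate 3, 0.0602 without replicate 1, and 0.0617 with only the 2 conditions compared) and Atf4 (0.69 ± 0.15) rose and Ddit4 fell (−1.07 ± 0.27). The cholesterol list did not pass without NT-3 replicate 3 (median 0.11, adjusted p = 0.110), and its median was 0.32 without NT-3 replicate 1. The stress list did not pass without PDGF replicate 5 (0.05001), NT-3 replicate 1 (0.163) or NT-3 replicate 3 (adjusted p = 0.0527), with the replicate number as a block (0.0657) or without the filter on signal (0.0753), and its median ranged from 0.14 to 0.35 leaving out samples. With quantile scaling neither list passed (adjusted p = 0.0581 and 0.0718). Other probe sets of Fdft1 (−0.95 and −0.71), Lss (−0.55), Atf4 (−0.26) and Sesn2 (−0.36) had the opposite sign, and none of the 4 passed as the mean of its probe sets (adjusted p from 0.239 to 0.861).

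Pdgfra was higher with NT-3 (0.74 ± 0.18, adjusted p = 0.0074; 10992 ± 1005 to 18608 ± 4474), but did not pass without NT-3 replicate 1 (0.55, adjusted p = 0.0602). Egfr was lower on the chosen probe set (−1.54 ± 0.24, adjusted p = 0.000478; 4348 ± 1501 to 1388 ± 97.8), and its other probe sets ranged from −1.39 to 0.88 (−0.63, adjusted p = 0.130, as the mean of all). Ntrk2 was higher on the chosen probe set (0.42 ± 0.11, adjusted p = 0.015) and lower on 4 others (−2.36 to −1.05, adjusted p from 3.73e-05 to 0.0459), so no direction is given for the gene. Without NT-3 replicate 3 the chosen probe set did not pass either (adjusted p = 0.0507). Ntrk3, the receptor for NT-3, did not pass on the chosen probe set (0.73 ± 0.45, adjusted p = 0.264), but was higher on the brighter probe set that a 75th percentile filter picks (0.51, adjusted p = 0.0428; 0.0693 when all probe sets passing the usual filter are tested). Ngfr did not differ detectably (0.78 ± 0.68, adjusted p = 0.443).

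Signs of RNA quality and of other cell types moved beside these groups. The 3' to 5' ratio of Actb on the first chip was higher with NT-3 (3.51 against 3.00 in log2, exact two-sided p = 0.0238, adjusted over the 12 such tests 0.0952). The smaller changes of the other ratios were 0.45 for Actb and 0.38 for Gapdh on the second chip (exact p = 0.0476 and 0.0357, adjusted 0.0952) and 0.15 for Gapdh on the first (exact p = 0.452). With 84 arrangements of these samples the exact p cannot fall under 0.0119, which leaves little room after adjustment. The median of 9 mural and mesenchymal genes was −0.87 (2 lower, 4 adjusted over the list alone, adjusted p = 0.132) and that of 9 ependymal and choroid plexus genes was −0.87 (3 lower, 5 adjusted over the list alone, adjusted p = 0.171), so neither list passed by camera. With the replicate number as a block the mural list did (−1.26, adjusted p = 0.0380), and by fry, which asks whether the genes of a list changed and not whether they changed more than other genes, both were lower (adjusted p = 0.00445 and 0.00188).

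Between EGF neurospheres and those grown with PDGF and NT-3, astrocyte, dorsal telencephalic and myelin genes were higher with EGF, and oligodendrocyte progenitor and cholesterol synthesis genes were higher with PDGF and NT-3. None of these lists passed when the correlation between genes was estimated (adjusted p = 0.0876, 0.0745, 0.278, 0.0601 and 0.134 with an estimated correlation). Factor, region and hybridisation batch all differ together here. With EGF relative to PDGF and NT-3, 1960 genes were higher and 1159 lower (3119 of 13882, 22.5%), of which 1620 differed at least 2-fold. With array weights 755 were lower.

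Mlc1 was higher with EGF (5.13 ± 0.33, adjusted p = 5.32e-08; 5117 ± 857 against 107 ± 85.2) and Mbp 30.9-fold higher (4.95 ± 0.24, adjusted p = 6.7e-10; 25552 ± 4791 against 803 ± 284). Tnnt1 (4.71 ± 0.49), Pla2g7 (4.48 ± 0.37; 31.4 ± 13.5 with PDGF and NT-3, under the pseudocount), Anxa5 (4.36 ± 0.40) and the junction protein Epb41l4a (4.34 ± 0.57; 5.28 without NT-3 replicate 2) followed. Pdgfra was 18.1-fold lower (−4.18 ± 0.18, adjusted p = 2.19e-10) and Sox10 10.1-fold (−3.34 ± 0.26, adjusted p = 3.22e-07), with Vgf (−3.51 ± 0.47), AW551984 (−3.33 ± 0.48), Atp10b (−3.33 ± 0.41) and Omg (−3.32 ± 0.46) beside them. Another probe set of Mbp, a dim one, gave −1.36, and other probe sets of AW551984 gave 0.23 and 1.20 (−0.63, adjusted p = 0.234, as the mean of all). Mlc1, Tnnt1 and Pla2g7 with NT-3 and Atp10b with EGF lay under the 25th percentile of the arrays, so their size rests on the pseudocount (4.30 to 5.82 for Mlc1 with others).

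By camera 8 of 28 lists shifted, and with an estimated correlation 0 did after adjustment and 6 at an unadjusted p under 0.05. Of 23 oligodendrocyte progenitor genes, 2 were higher and 13 lower with EGF (4 and 15 adjusted over the list alone; median −0.96, adjusted p = 1.21e-07, and adjusted p = 0.0601 with an estimated correlation). The proteoglycan Cspg4 was 9.39-fold lower (−3.23 ± 0.30) and Sox8 higher (2.46 ± 0.45; 1.58 without NT-3 replicate 1 and 3.12 without replicate 3). Of 17 genes of maturing oligodendrocytes and myelin, 7 were higher and 1 lower (8 and 2 adjusted over the list alone; median 0.52, adjusted p = 0.00954, and adjusted p = 0.278 with an estimated correlation). Mag (3.53 ± 0.29) and Mal (3.34 ± 0.33) were higher, against the low signals with NT-3 named above, and Bcas1 lower (−0.88 ± 0.19; −0.44, adjusted p = 0.195, as the mean of its probe sets). Of 18 astrocyte genes, 8 were higher and 0 lower (9 and 1 adjusted over the list alone; median 1.26, adjusted p = 0.000239, and adjusted p = 0.0876 with an estimated correlation). Aldh1l1, a folate enzyme of astrocytes, was 16.9-fold higher (4.08 ± 0.33, adjusted p = 3.9e-07; 5692 ± 1726 against 319 ± 192), beside Gja1 (3.35 ± 0.34), Slc4a4 (3.23 ± 0.27) and Id3 (1.98 ± 0.19). Of 7 dorsal telencephalon genes, 4 were higher (4 adjusted over the list alone; median 1.90, adjusted p = 0.00982, and adjusted p = 0.0745 with an estimated correlation). Emx2 was higher (3.44 ± 0.40, adjusted p = 1.6e-05; 2.92 to 4.07 with other pseudocounts), followed by Dmrta2 (2.68 ± 0.35), Lhx2 (2.19 ± 0.56) and Neurod1 (1.90 ± 0.35). Of 12 lateral ganglionic eminence genes, 6 were higher (6 higher and 1 lower adjusted over the list alone; median 0.83, adjusted p = 0.0180, and adjusted p = 0.0876 with an estimated correlation). Among them were Foxp2 (2.13 ± 0.35; 2.86 without NT-3 replicate 2; 0.090, adjusted p = 0.938, on another probe set that stands for it without the filter on signal), Foxp1 (1.69 ± 0.27; −0.31 on another probe set), Meis2 (1.65 ± 0.24) and Six3 (0.97 ± 0.23). Without NT-3 replicate 1, Six3 (0.71, adjusted p = 0.0508) and Lhx2 (1.59, adjusted p = 0.0702) did not pass. Without the filter on signal the dorsal and lateral lists did not pass (medians 0.59 and 0.64, adjusted p = 0.0525 and 0.0737), and the astrocyte median was 0.80.

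Cholesterol synthesis genes were lower with EGF in 8 and higher in 1 of 18 (10 and 1 adjusted over the list alone; median −0.49, adjusted p = 3.41e-05, and adjusted p = 0.134 with an estimated correlation). Lss 2.36-fold (−1.24 ± 0.16), Fdft1 (−1.16 ± 0.15; 0.90 and 1.19 on other probe sets, and −0.075, adjusted p = 0.862, as the mean of all) and Sqle (−0.95 ± 0.17) fell. Fdps was higher (0.55 ± 0.19, adjusted p = 0.0457), a call that many alternatives ended. Genes of endoplasmic reticulum and amino acid stress were lower in 4 of 19 (5 adjusted over the list alone; median −0.32, adjusted p = 0.00370, and adjusted p = 0.0685 with an estimated correlation). They were Sesn2 (−1.80 ± 0.30), Atf4 (−1.08 ± 0.15), Asns (−0.89 ± 0.14) and Vldlr (−0.61 ± 0.19; 0.67 on another probe set). Cell cycle genes were lower in 5 and higher in 1 of 31 (5 and 1 adjusted over the list alone; median −0.25, adjusted p = 0.0118, and adjusted p = 0.403 with an estimated correlation). The list did not pass without NT-3 replicate 1 or 3 (medians −0.21 and −0.14, adjusted p = 0.0649 and 0.117). Bub1 (−1.22 ± 0.26; 0.13 on another probe set, and −0.54, adjusted p = 0.179, as the mean of its probe sets), Mcm5 (−0.69 ± 0.17) and Mcm7 (−0.44 ± 0.13) were lower and Cdca8 was higher (0.64 ± 0.18; 0.31 without NT-3 replicate 2, and −0.31 and −0.35 on other probe sets). With the replicate number as a block Cdca8 did not pass (0.61, adjusted p = 0.0506), nor with only the 2 conditions compared (0.05004). Calls were also lost for Mcm5 without NT-3 replicate 3 (adjusted p = 0.0506), Mcm7 without NT-3 replicate 1 or 3 (adjusted p = 0.106 and 0.126), with quantile scaling (−0.26, adjusted p = 0.0923), median centring (0.0536) or no trend (0.0592), and Vldlr without NT-3 replicate 1 or 2 (adjusted p = 0.149 and 0.0595) or with array weights (0.0540). Fdps did not pass without NT-3 replicate 1 (0.26, adjusted p = 0.310) or without any EGF replicate but 3 (adjusted p from 0.0512 to 0.0807). Nor did it pass with the replicate number as a block (0.50, adjusted p = 0.141), median centring (0.129), only the 2 conditions compared (0.107), quantile scaling (0.0557), no filter (0.0544), no trend (0.0541) or array weights (0.0525).

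Egfr was higher with EGF than with PDGF and NT-3 on the chosen probe set (1.22 ± 0.24, adjusted p = 0.00166). Of its other probe sets 2 passed with larger values (2.37, adjusted p = 0.00863, and 2.87, adjusted p = 9.07e-08), and the others ranged from −0.15 to 1.45. Ntrk2 was higher (0.71 ± 0.11, adjusted p = 0.000249), while Ngfr did not pass (−0.83 ± 0.68, adjusted p = 0.404). Ntrk3 did not pass on the chosen probe set (−1.11 ± 0.45, adjusted p = 0.0846), but was lower with EGF on the one that a 75th percentile filter picks (−1.14, adjusted p = 0.000211). The 3' to 5' ratios were lower with EGF: −0.67 for Actb and −0.50 for Gapdh on the second chip (exact two-sided p = 0.0119 for both, adjusted 0.0714), −0.53 for Actb on the first (exact p = 0.0476) and −0.26 for Gapdh on the first (exact p = 0.25). An exact p of 0.0119 is the smallest that 84 arrangements can give. The medians of mural genes (0.70, adjusted p = 0.252) and ependymal genes (0.81, adjusted p = 0.115) lay on the EGF side without passing by camera, and both passed by fry (adjusted p = 0.00527 and 0.000373).

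**Figure D3:**
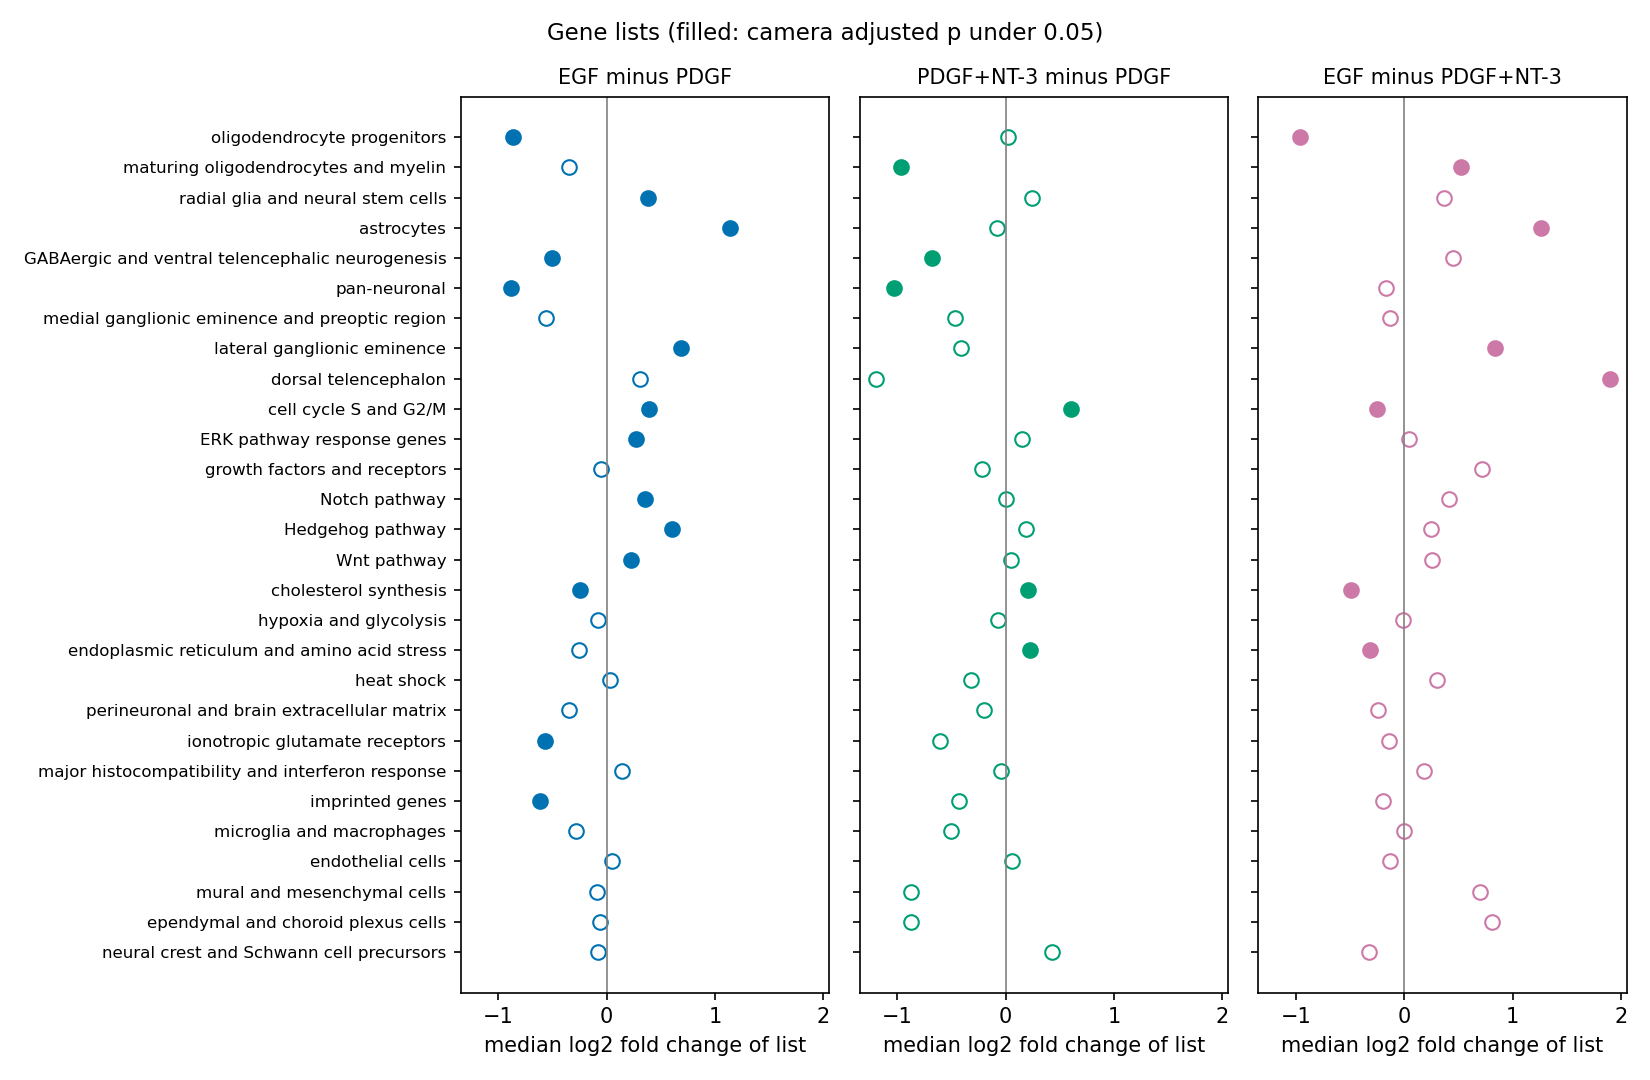
Median log2 fold change (horizontal axis) of each of 28 gene lists (vertical axis) in the 3 comparisons, 1 point per list, filled where the camera adjusted p is under 0.05. Oligodendrocyte progenitors lie at −0.86 and −0.96 in the comparisons with EGF and at 0.03 between the PDGF conditions, where myelin genes lie at −0.97 and cell cycle genes at 0.60.

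The genes called in EGF against PDGF and in EGF against PDGF with NT-3 overlapped: 476 were higher and 372 lower with EGF in both, and 44 were opposite. Both comparisons use the same EGF samples. The fold changes correlated across genes with r = 0.446 (covariance 0.193), and in 20 simulations without any effect the shared samples alone gave r = 0.409 (covariance 0.0522) and 0 shared calls. These simulations held no changed genes, so the 0 does not show how many shared calls the common EGF samples add among changed genes. They also gave all conditions the same spread. Independent lists of these sizes would share 127 higher and 75.6 lower genes, numbers that leave the shared samples out of account. With the EGF samples split so that no sample served both comparisons, 316 higher and 205 lower genes were shared in the first split (r = 0.329, covariance 0.156) and 302 and 214 in the second (r = 0.263, covariance 0.130).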

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

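The tests of hybridisation batch, scaling, signal trend, other probe sets, brain region and progenitor share were chosen after the result was seen. Those of dim genes and fluidics runs were added once the data had been seen, with their bounds set before their own values were known, and the regrouping of samples was planned.

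In groups of 6 samples, a sample was singled out when its gap to the nearest other was larger, as a share of the group's range, than Dixon's critical value for 6 samples. This happened in 24 of 280 groups, and chance gives about 1 in 20 (14 here). With EGF these were, as gap ratios, Anxa5 (replicate 2, 0.727), Cdc6 (6, 0.647), Dhcr7 (6, 0.685), Dll3 (6, 0.658), Elavl3 (3, 0.762), Enpp6 (1, 0.784), Gria3 (1, 0.781), Hr (4, 0.655), Mbp (2, 0.683), Sting1 (2, 0.680), Vgf (5, 0.775), Vldlr (4, 0.860) and the Actb 3' to 5' ratio on the second chip (4, 0.638). With PDGF they were 1700003E16Rik (replicate 1, 0.644), 4930503L19Rik (6, 0.631), Atp10b (1, 0.662), Cort (5, 0.816), Gria2 (2, 0.646), Nnat (6, 0.818), Parvb (2, 0.768), Pla2g7 (3, 0.708), Ptn (4, 0.640), Sqle (6, 0.626) and the Gapdh ratio on the second chip (1, 0.753).

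The B2 repeat control probe set, used in no comparison of genes, was 0.48 higher in log2 on the first chip with NT-3 than with PDGF (171291 ± 21194 against 122952 ± 14776 in signal, and 110316 ± 16432 with EGF). The exact two-sided p was 0.0119, the smallest that 84 arrangements can give.

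More genes were lower than higher with PDGF and NT-3 against PDGF (65.0% lower). Genes were ranked by mean signal into 3 equal parts. Of the calls in the brightest part 53.0% were lower, against 74.2% in the middle and 80.5% in the dimmest. Leaving out single samples gave 51.0% to 57.9% for the brightest part. The 53.0% met the bound set beforehand for noise or background of dim genes. This division cannot tell noise or background from real decreases of dim genes, so it does not settle the cause of the excess. Scaling stays open, because the scalings differ: quantile scaling gave 63.5% lower calls (62.0% to 70.1% leaving out single samples), which argues against it, and median centring 58.5%, but 49.7% without PDGF replicate 6. The hybridisation batch cannot be told apart from NT-3, since 0 arrays with NT-3 share a run with another condition.

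Maturing oligodendrocyte and myelin genes were lower with PDGF and NT-3 against PDGF. A trend with signal level alone is argued against, since the list's median lay at percentile 0.02 of random lists of matched signal. Of 22 other probe sets of 8 of these genes, 63.6% were negative, 6 passing lower and 0 higher, but 7 belong to Mbp; of the other 15, 53.3% were negative and 2 passed, which leaves single faulty probe sets open for part of the list. The hybridisation batch (0 shared runs) stays open as well, as does an effect of NT-3 on the cells, for which there was no separate test. Under an estimated correlation the list did not pass (adjusted p = 0.0917).

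Oligodendrocyte progenitor genes were lower and astrocyte genes higher with EGF against PDGF. Differences between fluidics runs are argued against, as the progenitor median closest to 0 among the runs was −0.85. A lower share of progenitors alone would raise the markers of all other cell types, but the pan-neuronal median was −0.89, which argues against it only as far as that list's call goes (adjusted p = 8.56e-09, but adjusted p = 0.134 with an estimated correlation). The brain region, ganglionic eminences against entopeduncular area, cannot be told apart from the factor, since 0 regions were grown with both.

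The number of genes called was set against other splits of the samples, and the real split gave the most in each comparison. Such splits cannot tell a condition from a batch or a shared culture that goes with it. The real split gave 1807 genes for EGF against PDGF and the highest of 100 drawn from 462 possible splits otherwise 2 (1 split gave as many). It gave 2943 for PDGF with NT-3 against PDGF and the highest other 65 (1 of 84 gave as many), and 3119 for EGF against PDGF with NT-3 and the highest other 7 (1 of 84). The share of lower calls and the gene lists were not scored on these splits.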

How the results depend on the processing

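The comparison within single fluidics runs, the division by signal level and the matched random lists were added after the data were seen, the run and signal divisions with their bounds set before their own values were known; the other alternatives were fixed earlier. Where a value changed, the cause was not tested unless the change follows from the alternative itself, as with fewer samples, more probe sets tested, a 2-fold minimum or another probe set standing for the gene.

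With the alternatives that keep 1 value per gene and the 0.05 threshold, the genes called numbered 1484 to 2231 for EGF against PDGF, 1897 to 3220 for PDGF with NT-3 against PDGF and 2151 to 3332 for EGF against PDGF with NT-3. These stayed within 1.5 times the reported counts except with array weights, which left 616 higher and 1897 in total for PDGF with NT-3 against PDGF and 755 lower for EGF against PDGF with NT-3. At least 2-fold left 365 higher and 329 lower (694), 316 and 1138 (1454), and 1177 and 443 (1620) in the 3 comparisons. All probe sets gave 1859 higher and 3222 lower (5081) for PDGF with NT-3 against PDGF, and 3266 and 2049 (5315) for EGF against PDGF with NT-3. With the replicate number as a block (replicate block) the totals were 1735, 2643 and 2865, and 2324 of the 2943 genes of PDGF with NT-3 against PDGF were called both ways. Within runs 220, 291 and 270 genes were higher and 134, 164 and 225 lower for EGF against PDGF. The overlap of the comparisons with EGF fell to 521 and 516 with separate EGF samples.

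Same-numbered EGF and PDGF samples resembled each other slightly: across genes, after the condition means were removed, r was 0.0165 to 0.110, and 5 of 6 EGF samples matched best their own number. Samples with NT-3 gave r of −0.0352 to 0.0514 with same-numbered PDGF samples and −0.0215 to 0.0445 with EGF samples. These values lie on both sides of 0, so they show no pairing for the replicate block in the comparisons with NT-3.

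Leaving out each sample gave 761 to 866 higher and 737 to 922 lower genes (1516 to 1782 in total) for EGF against PDGF, 662 to 1061 and 1533 to 1897 (2195 to 2958) for PDGF with NT-3 against PDGF, and 1717 to 1839 and 841 to 1122 (2558 to 2961) for EGF against PDGF with NT-3. The 662 came without NT-3 replicate 1. Lists past the threshold numbered 13 to 15, 4 to 6 and 7 to 8.

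With an estimated correlation 3, 0 and 0 lists passed in the 3 comparisons, against 14, 6 and 8 with the preset one. At an unadjusted p under 0.05 the estimated correlation gave 11, 5 and 6. These 5 include the dorsal telencephalon and ERK lists, which the preset correlation did not call. Fry gave 18, 13 and 16 after adjustment within each comparison alone, a smaller family than that of camera. Apart from that, list calls changed as follows, each with the range of adjusted p over all its alternatives. The ERK list for EGF against PDGF ended without PDGF replicate 1, 4 or 5 or EGF replicate 6 (0.0380 to 0.154). The Hedgehog (9.94e-05 to 0.142) and Wnt lists (0.0230 to 0.219) ended without the filter. The medial ganglionic eminence list was gained without PDGF replicate 2 or 6 or EGF replicate 1, 5 or 6, with values of 0.0302 to 0.0465 (0.0302 to 0.330). For PDGF with NT-3 against PDGF, cholesterol synthesis ended with quantile scaling and without NT-3 replicate 3 (0.00554 to 0.347). Endoplasmic reticulum stress ended without the filter, with quantile scaling, with the replicate block (0.0657) and without PDGF replicate 5 or NT-3 replicate 1 or 3 (0.00811 to 0.163). The mural list was gained with the replicate block (0.0380; 0.0380 to 0.479). For EGF against PDGF with NT-3, radial glia was gained with quantile scaling (0.0277 to 0.275), the lateral (0.0110 to 0.0876) and dorsal lists (0.00700 to 0.0745) ended without the filter, and the cell cycle ended without NT-3 replicate 1 or 3 (0.000380 to 0.403).

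The named genes' log2 fold changes kept direction and side of the threshold in 2375 values under changed settings (42 lost the call, 9 reversed and 3 gained it, all 3 being Ntrk3 with the 75th percentile filter: −0.62, 0.51 and −1.14) and in 1779 leaving out samples (31 lost it, 0 gained it, 5 reversed). Among other probe sets of the same genes 89 kept both, 71 lost the call, 5 gained it and 47 reversed. Of 92 calls with other probe sets, 49 had another that passed in the same direction and 1, Ntrk2, had others that passed in the opposite direction.

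Reversed values for EGF against PDGF, on other probe sets: Car3 −0.0078, Lrig1 −0.023, Foxp1 −0.45, Notch2 −0.10, Smo −1.30, Wnt7a −0.26, Srebf2 0.089, Egfr 3.25, 3.18, 0.061 and 0.085 (0.53 as the mean of its probe sets), Ntrk2 −0.47, −0.84, −0.20 and −0.70. Without the filter Cdon gave −0.27 and Gli3 −0.26, and with the 75th percentile filter Wnt7a gave −0.26. Ngfr, not called, ranged from −0.37 to 0.26 leaving out samples.

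For PDGF with NT-3 against PDGF, without the filter: Eepd1 −0.50, Pik3cd −0.76, Parvb 0.034 and Maf 0.92. On other probe sets: Pik3cd −0.16, Depp1 −0.32, Sparc −0.17, Mbp 0.62, Mal 0.34, Rtel1 0.24, Fdft1 −0.95 and −0.71, Lss −0.55, Atf4 −0.26, Sesn2 −0.36, Egfr 0.88, 0.30 and 0.24, Ntrk3 −0.68, Ntrk2 −0.14, −2.36, −2.23, −2.09 and −1.05.

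For EGF against PDGF with NT-3, on other probe sets: Mbp −1.36, AW551984 0.23 and 1.20, Foxp1 −0.31, Bub1 0.13, Cdca8 −0.31 and −0.35 (−0.0080 as the mean of its probe sets), Fdft1 0.90 and 1.19, Vldlr 0.67, Egfr −0.15 and Ntrk3 0.59.

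Signal over background limits the dim genes: the 25th percentile of the first chip was 143 ± 12.5 with NT-3, 175 ± 30.0 with PDGF and 174 ± 10.6 with EGF, and the pseudocount was 52.0.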

Other observations

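The matched random lists and the counts of unnamed probe sets were chosen after the data were seen. By camera, myelin genes did not shift as a group between EGF and PDGF neurospheres: 2 of 17 were higher and 3 lower with EGF (2 and 4 adjusted over the list alone; median −0.35, adjusted p = 0.169). Genes of the medial ganglionic eminence and preoptic region had medians of −0.56 for EGF against PDGF (adjusted p = 0.0620), −0.47 for PDGF with NT-3 against PDGF (adjusted p = 0.450) and −0.13 for EGF against PDGF with NT-3 (adjusted p = 0.507). Dorsal telencephalon genes had medians of 0.31 (adjusted p = 0.135) and −1.19 (adjusted p = 0.0782) in the first comparisons, and lateral ganglionic eminence genes −0.41 with NT-3 against PDGF (adjusted p = 0.662). Radial glia genes had medians of 0.24 with NT-3 against PDGF (6 higher, 4 lower of 21, adjusted p = 0.230) and 0.37 for EGF against PDGF with NT-3 (9 higher, 2 lower, adjusted p = 0.0968). Whether a list's shift differs between comparisons was not tested.

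In the order EGF against PDGF, PDGF with NT-3 against PDGF, and EGF against PDGF with NT-3, these lists did not pass by camera in any comparison. Growth factors and receptors had medians of −0.06, −0.22 and 0.71 (adjusted p = 0.558, 0.793 and 0.258), hypoxia and glycolysis −0.08, −0.07 and −0.02 (0.426, 0.670 and 0.670), and heat shock 0.03, −0.32 and 0.30 (0.450, 0.670 and 0.483). Brain extracellular matrix genes had medians of −0.35, −0.20 and −0.24 (0.0864, 0.793 and 0.343), and histocompatibility and interferon genes 0.14, −0.04 and 0.18 (0.435, 0.933 and 0.608). Lists that passed by camera elsewhere had medians as follows in the comparisons where they did not: astrocytes −0.08 with NT-3 against PDGF (0.305), endoplasmic reticulum stress −0.26 for EGF against PDGF (0.159), ERK genes 0.16 and 0.05 (0.0637 and 0.775), Notch 0.00 and 0.41 (0.450 and 0.285), Hedgehog 0.19 and 0.25 (0.349 and 0.172), Wnt 0.05 and 0.26 (0.407 and 0.609), glutamate receptors −0.61 and −0.14 (0.319 and 0.435) and imprinted genes −0.43 and −0.20 (0.450 and 0.292), the last 6 with NT-3 against PDGF and then EGF against PDGF with NT-3. In EGF against PDGF with NT-3, pan-neuronal genes had a median of −0.17 (0.628) and GABAergic genes 0.45 (0.612).

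Lists of other cell types did not pass by camera either. In the same order, microglia and macrophages had medians of −0.28, −0.51 and 0.00 (adjusted p = 0.450, 0.426 and 0.793), endothelial cells 0.05, 0.06 and −0.13 (0.918, 0.793 and 0.854), and neural crest and Schwann cell precursors −0.08, 0.43 and −0.32 (0.662, 0.628 and 0.558). Mural and ependymal genes had medians of −0.09 and −0.06 for EGF against PDGF (0.933 and 0.793); with NT-3 against PDGF their medians lay at percentiles 2.16 and 2 of random lists of matched signal. By fry, which asks whether the genes of a list changed and not whether they changed more than other genes, some lists that camera did not call passed. For EGF against PDGF these were the medial ganglionic eminence (adjusted p = 0.00190), dorsal telencephalon (0.00101), endoplasmic reticulum stress (0.00505) and extracellular matrix lists (0.00315). With NT-3 against PDGF they were the dorsal (5.43e-05), ERK (0.0141), heat shock (0.00302), glutamate receptor (0.00302), microglia (0.00636), mural (0.00445) and ependymal lists (0.00188). For EGF against PDGF with NT-3 they were the radial glia (5.54e-05), growth factor (0.0205), Notch (0.00157), Hedgehog (0.000350), Wnt (0.000404), heat shock (0.000350), mural (0.00527) and ependymal lists (0.000373). The 2 genes of red blood cells, not tested by camera, had medians of 0.10, −0.53 and 0.63 and no call.

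The median, the mean and camera's direction differed in sign for some of these lists. For EGF against PDGF they did so for growth factors (mean 0.14, camera up) and ependymal genes (mean 0.10, up). With NT-3 against PDGF they did so for oligodendrocyte progenitors (mean −0.15, up), astrocytes (mean 0.10, up), growth factors (mean −0.20, up), Wnt (mean −0.07, up), histocompatibility (mean −0.09, up), endothelial (mean −0.03, up) and neural crest genes (mean −0.07, up). For EGF against PDGF with NT-3 they did so for pan-neuronal (mean 0.12, down), ERK (mean 0.12, down), microglia (mean 0.20, up) and endothelial genes (mean 0.06, down).

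Sex-linked genes, used only to check samples, ranged from 5029 to 19290 for Xist, 175 to 1410 for Eif2s3y and 85.4 to 1545 for Uty over the 15 samples. Probe sets without a single gene symbol were counted in the fit of all 29696 probe sets, with p-values adjusted over all of them. Of 6197, 80 were higher and 95 lower for EGF against PDGF, 271 and 608 for PDGF with NT-3 against PDGF, and 554 and 303 for EGF against PDGF with NT-3. The median signal of arrays of the first chip ranged from 456 to 672 with PDGF, 526 to 582 with EGF and 475 to 542 with NT-3.

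The 3' to 5' ratios of EGF and PDGF samples differed by −0.11 and −0.12 for Gapdh and by −0.02 and −0.22 for Actb on the first and second chip (exact two-sided p = 0.277, 0.316, 0.913 and 0.126). None of the 12 ratio tests passed after adjustment. In the comparisons with NT-3 the exact p cannot fall under 0.0119 (84 arrangements), which leaves little room after adjustment. That none passed therefore does not show that RNA quality was alike with and without NT-3.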
